A study of Mus musculus with 17 samples.

How the data were processed

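Gene expression was measured in epithelial cells from the colon of isogenic C57BL/6 mice, taken before culture and at 3 later stages of growth in medium with reduced serum, in which the cells became immortal and then transformed without any added agent, per the labels. Total RNA was extracted on columns, labelled with Cy3 and hybridised to 1-colour Agilent whole-genome mouse arrays, per the labels' protocols. The 17 arrays fall into 4 groups taken from the labels: 3 uncultured, 4 preimmortal (passages 3 to 5), 3 immortal (passages 6 to 8) and 7 late transformed (passages 51 to 66). A code such as F1K recurs across stages and was read as naming a line, which the labels do not state.

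For each array the authors deposited a scanner file whose spot intensity had been background-subtracted and detrended over the array by Agilent Feature Extraction, version 10.5.1.1 for most arrays, version 9.5.3.1 for late transformed F4K, whose file names build mm8, and version 10.7.1.1 for late transformed M2K and the array labelled late transformed F3K, per the file headers. The same files hold other values, namely 0 or 1 calls of outlier, saturated and well-above-background spots, per the file headers. That of preimmortal F3K gives 3 significant digits. The authors also deposited a table of log2 values per probe, with a normalization, scale and centring that are not stated in the sources used here. Its column medians lie between 7.90 and 8.53, and its highest value, 24.4, lies above the highest log2 value of the scanner files, 19.5, so sizes of change from it have no known scale, and apart from its directions, calls and adjusted p-values they are given only for results that reversed and for sex-linked genes. The columns of 9 arrays followed their scanner file at r of at least 0.99 across probes, and those of the other 8 did not: late transformed F1K, F2K, M1K, F4K and M2C (r = 0.828 to 0.967) and the arrays labelled uncultured F1K, F2K and M2K (r = 0.844, 0.896 and 0.727). Of the 8, uncultured F1K and F2K matched the deposited column of uncultured M2K best (r = 0.866 and 0.901) and uncultured M2K matched that of late transformed F4K best (r = 0.946). Genes are not independent replicates in these correlations.

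The values analysed are log2 of the processed signal minus the 75th percentile of that array, over 43379 non-control spots and 41174 probes. Outlier spots were left out, saturated spots were kept, and spots of the same probe were averaged. A probe was kept if it was well above background on at least 3 arrays, which held for 29546 probes, and a gene was represented by its brightest kept probe, giving 20203 genes. Accessions of 25097 probes matched the reference gene table, which was used for symbols only, and other probes keep the name in the files. Probe positions are those of build mm9 in the other files. Where a called gene had several kept probes, a probe of opposite sign occurred for 207 of 952 genes in preimmortal against uncultured, 5 of 53 in late transformed against immortal, 61 of 569 in late transformed against preimmortal and 111 of 743 in late transformed against uncultured. A gene bright only on uncultured F1K and F2K fails the filter of 3 arrays and was not tested.

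Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of 4 groups over 17 arrays without a block, with Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05. Figures were drawn and files read with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Errors of log2 differences are standard errors (SE) of the fit, which pools the spread of all groups, and errors of levels are SDs. Samples of different lines come from different mice as far as the codes show, except that M2K and M2C share M2, with no relation given, and the number of arrays limits the precision. Where a called gene was not well above background on any array of the dimmer group, or on only some of them, the difference is given as "at least N-fold": the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the gene's own signal and the lowest signal that was well above background. Genes that did not pass are given as such a bound or as the fitted difference, the latter also where 5 or 6 of 7 late transformed or 3 of 4 preimmortal arrays measured them.

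Shifts of 29 gene lists with 556 members and of the genes of 20 chromosomes (20038 genes) were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists or chromosomes of a comparison. With an estimated correlation, none of the list or chromosome calls held. List medians are given relative to the median over all genes of the comparison, because scalings moved that median by more than 0.1. The lists were written from general knowledge, not from these samples. Named genes were taken by a rule: the 5 called genes with the largest rise and fall among those measured on every array, the 4 with the largest bounds in each direction, called members of called lists with the smallest adjusted p, and 22 key genes. Some genes taken by this rule are not reported here. The narrowing from up to 4 members of a called list to 2, and the selection by hand it replaced, were made after values had been seen. The groups, lists, naming rule, tests and most alternatives were fixed before the data were examined.

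The test was checked on simulated data with the spread of these arrays. In preimmortal against uncultured, 22.4% of 4-fold and 68.2% of 16-fold changes were recovered among 20203 genes. In the other comparisons the shares ran from 11.9% and 62.1% for immortal against preimmortal to 32.8% and 81.8% for late transformed against uncultured. Of 2-fold changes 0% to 2.99% were recovered. Beside the changes, 2 to 8 unchanged genes were called (7 in late transformed against immortal), against 0 without any change. Other splits of the real arrays called up to 8512 genes, so these counts are not their error rate.

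The code was taken to pair arrays, although 5 of 16 pairs of the same code join an array with Ddx3y above background to one without. Over these 16 pairs in different groups, the correlation of deviations from the group means had a median of 0.03 (from −0.14 to 0.52), against −0.01 over 87 pairs of different lines. The consensus correlation was 0.0313 within lines and 0.0108 within slides. The arrays lie on 8 slides scanned on 6 days, and slides 3, 4, 5 and 6 and scan day 4 hold more than 1 group. Alternatives were normexp background correction (offset 50), quantile normalization, median centring, a 75th percentile over probes well above background on all arrays, other probe filters, the mean of a gene's probes, other moderation including array weights, only the 2 groups compared, line, slide and sex as terms, the deposited table, leaving out the 3 late transformed arrays of another Feature Extraction version, and leaving out each array in turn. Others were chosen after seeing the data.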

Results

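RNA from cells of C57BL/6 mice, colon epithelial per the labels, was profiled on 17 arrays at 4 stages. There were 3 arrays of uncultured cells, which the labels call the normal control, 4 of preimmortal cells, 3 of immortal cells and 7 of late transformed cells. The series sets these stages beside the development of human colon cancer. Between 50.5% and 73.5% of spots were well above background on 16 arrays, and 27.4% on late transformed F1K. Gene levels are log2 signals relative to the 75th percentile of the array.

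Lgals4, a galectin of the intestinal epithelium, reached 7.83 on uncultured F1K and 9.11 on uncultured F2K but 0.35 on uncultured M2K. Muc2, the main mucin of goblet cells, reached 3.43, 3.89 and −4.39. Lct, the lactase of the small intestinal brush border, reached 2.15, 7.44 and −2.47. Across genes, which are not independent replicates, uncultured M2K correlated with the mean of the 14 cultured arrays at r = 0.959 and with the mean of the other 2 uncultured arrays at r = 0.75. Sex-linked transcripts went against the label on 3 arrays. Uncultured F1K, labelled female, had the Y-linked Ddx3y at 0.09 and Xist, the transcript of the inactive X chromosome, at −3.46. Uncultured M2K, labelled male, had Xist at 5.70 and Ddx3y at −7.20, and late transformed F3K, labelled female, had Ddx3y at −0.56 and Xist at −4.00. Late transformed M2K, labelled male, had neither Xist (−6.35) nor Ddx3y (−6.48) above background, and late transformed M2C, labelled male, had both (−1.16 and 0.90). The first 3 are called the arrays labelled uncultured F1K, uncultured M2K and late transformed F3K, and they stay in their groups. Directions against uncultured cells are drawn from 2 of them, so they hold for the arrays so labelled.

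The first comparison asks what the first passages in culture changed. Epithelial transcripts fell in preimmortal cells. Lgals4 fell by 7.34 ± 1.43 (SE) on the log2 scale (adjusted p = 0.0045), from 5.76 ± 4.73 (SD, n = 3) to −1.58 ± 0.45 (n = 4, limma). Krt18, a keratin of simple epithelia, was at least 833-fold lower (adjusted p = 0.001), where "at least" gives a bound because only 2 of 4 preimmortal arrays measured it. Transcripts of mesenchymal cells rose, with Lox, which cross-links collagen, up by 6.03 ± 0.84 (adjusted p = 0.000813) to 5.33 ± 0.32 (n = 4, limma). The probes lie on chromosome 7 at 29626658 to 29626717 (Lgals4), chromosome 15 at 101862341 to 101862400 (Krt18) and chromosome 18 at 52676167 to 52676226 (Lox) of mm9. 3558 of 20203 genes were called, 1198 higher and 2360 lower, with a median over all genes of −0.24.

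Of 20 epithelial junction and keratin genes, 10 fell and 10 did not pass, and 14 fell adjusted over the list alone. The list median was −3.80 relative to all genes (adjusted p = 0.00021, or adjusted p = 0.437 with an estimated correlation). The adherens junction gene Cdh1 was at least 39.7-fold lower (adjusted p = 0.0209) and the transcription factor Grhl2 at least 13.9-fold (adjusted p = 0.0186), both measured on 0 of 4 preimmortal arrays. Of 13 absorptive colonocyte markers 9 fell and 4 did not pass, with 9 lower adjusted over the list alone and a relative median of −5.50 (adjusted p = 0.000273, or adjusted p = 0.437 with an estimated correlation). Guca2a, the precursor of guanylin, changed by −6.19 ± 1.57 (adjusted p = 0.0167), and the chloride exchanger Slc26a3 was at least 36.5-fold lower (adjusted p = 0.023, measured on 2 of 4). Of 10 goblet and secretory markers 8 fell and 2 did not pass, with 9 lower adjusted over the list alone and a relative median of −7.36 (adjusted p = 0.001, or adjusted p = 0.437 with an estimated correlation). Muc2 was at least 85.8-fold lower (adjusted p = 0.0071, measured on 1 of 4), Spink4 at least 104-fold (adjusted p = 0.0135, 0 of 4) and Zg16 at least 168-fold (adjusted p = 0.0197, 3 of 4).

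Of 9 enteroendocrine markers 2 fell and 7 did not pass, with 4 lower adjusted over the list alone and a relative median of −2.40 (adjusted p = 0.0184, or adjusted p = 0.437 with an estimated correlation, and 0.0797 without uncultured F2K). The hormone gene Pyy was at least 34.5-fold lower (adjusted p = 0.0213, 3 of 4) and the granule gene Chga at least 40.0-fold (adjusted p = 0.0398, 3 of 4). Of 10 intestinal transcription factors 5 fell and 5 did not pass, with 7 lower adjusted over the list alone and a relative median of −2.91 (adjusted p = 0.0205, or adjusted p = 0.437 with an estimated correlation), and the call was lost without uncultured F2K (0.0797) and without late transformed F2K (0.0518). Cdx2 was at least 43.7-fold lower (adjusted p = 0.0219, 0 of 4). Of 30 genes lower in human colorectal tumours 11 fell and 19 did not pass, with 14 lower and 1 higher adjusted over the list alone and a relative median of −1.74 (adjusted p = 0.0037, or adjusted p = 0.442 with an estimated correlation, and 0.0795 without uncultured F2K). Among them the steroid dehydrogenase gene Hsd17b2 was at least 22.7-fold lower (adjusted p = 0.0121, 0 of 4). These epithelial lists were high on the arrays labelled uncultured F1K and F2K, where the small intestinal Lct was high too, and not on uncultured M2K.

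Markers of blood-borne and vessel cells fell. Of 15 leukocyte markers 5 fell and 10 did not pass, with 9 lower adjusted over the list alone and a relative median of −2.96 (adjusted p = 0.0032, or adjusted p = 0.437 with an estimated correlation). The actin regulator Coro1a changed by −5.34 ± 1.27 (adjusted p = 0.0124), and Cd74, the class II invariant chain, was at least 57.4-fold lower (adjusted p = 0.0243, 3 of 4). Of 13 endothelial markers 4 fell and 9 did not pass, with 8 lower adjusted over the list alone and a relative median of −2.93 (adjusted p = 0.0038, or adjusted p = 0.437 with an estimated correlation). Robo4 was at least 333-fold lower (adjusted p = 0.0014, 3 of 4), Vwf changed by −4.81 ± 1.49 (adjusted p = 0.0373) and Egfl7 by −3.17 ± 0.67 (adjusted p = 0.0066). Neither list lay lower within slide 6, against the array labelled uncultured M2K. Of 23 interferon response genes 6 fell and 17 did not pass, with 6 lower adjusted over the list alone and a relative median of −1.84 (adjusted p = 0.0056, or adjusted p = 0.496 with an estimated correlation). The call was lost without uncultured M2K (0.162), without both that array and late transformed F1K (0.284) and in the deposited table (0.41). The chemokine Cxcl10 changed by −4.16 ± 1.04 (adjusted p = 0.0157), the immunoproteasome subunit Psmb9 by −4.44 ± 1.06 (adjusted p = 0.0124), and Oas1a was at least 44.9-fold lower (adjusted p = 0.0262, 2 of 4).

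Of 22 mesenchymal and EMT genes (of the epithelial-mesenchymal transition) 10 rose and 12 did not pass, with 13 higher adjusted over the list alone and a relative median of 2.58 (adjusted p = 8.34e-09, or adjusted p = 0.437 with an estimated correlation). Besides Lox, the integrin Itgb1 rose by 2.33 ± 0.47 (adjusted p = 0.0054), the receptor kinase Axl by 2.91 ± 0.63 (adjusted p = 0.0074), the repressor Zeb1 by 2.30 ± 0.56 (adjusted p = 0.0133) and N-cadherin, Cdh2, by 2.68 ± 0.78 (adjusted p = 0.0298). The intermediate filament gene Vim differed by 1.25 ± 0.54 (adjusted p = 0.108). Of 17 fibroblast and myofibroblast markers 2 rose, fibrillin Fbn1 by 3.53 ± 0.54 (adjusted p = 0.0011) and Sparc by 2.36 ± 0.68 (adjusted p = 0.029). The other 15 did not pass, and 2 were higher adjusted over the list alone, at a relative median of 1.61 (adjusted p = 0.0065, or adjusted p = 0.437 with an estimated correlation, and 0.0797 without uncultured F2K). Of 16 glycolysis genes 2 rose, Hk1 by 1.82 ± 0.58 (adjusted p = 0.0405) and Eno1 by 2.04 ± 0.46 (adjusted p = 0.0095). The other 14 did not pass, and 5 were higher adjusted over the list alone, at a relative median of 1.86 (adjusted p = 0.00021, or adjusted p = 0.437 with an estimated correlation). In the deposited table the list did not pass (adjusted p = 0.971) and Hk1 lay lower (adjusted p = 0.141).

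Of 22 p53 targets 5 rose and 17 did not pass, with 5 higher adjusted over the list alone and a relative median of 1.21 (adjusted p = 0.0038, or adjusted p = 0.437 with an estimated correlation). The receptor gene Eda2r was at least 8.97-fold higher (adjusted p = 0.0279, measured on 1 of 3 uncultured arrays). Zmat3 rose by 2.76 ± 0.75 (adjusted p = 0.0227), but differed by −0.36 with the mean of its probes. Of 22 oncogenes of colorectal cancer 4 rose and 18 did not pass, with 4 higher adjusted over the list alone and a relative median of 0.91 (adjusted p = 0.015, or adjusted p = 0.437 with an estimated correlation), and the call was lost without uncultured F1K (0.107) or F2K (0.0795) and in the deposited table (0.214). The growth factor receptor Egfr rose by 2.61 ± 0.72 (adjusted p = 0.0236) and the cyclins Ccnd2 by 2.29 ± 0.61 (adjusted p = 0.0204) and Ccnd1 by 2.57 ± 0.77 (adjusted p = 0.0334).

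Other large rises were those of Adcyap1r1 (5.82 ± 1.29, adjusted p = 0.0088), Crct1 (6.91 ± 1.03, 0.000958) and Kprp (6.70 ± 1.06, 0.0013). Lce1g, of the cornified envelope, was at least 115-fold higher (adjusted p = 0.0045), Folh1 at least 86.7-fold (0.001), Olr1 at least 73.8-fold (0.0148) and Prl8a2 at least 28.2-fold (0.0024), each measured on 0 of 3 uncultured arrays. Lct was at least 232-fold lower (adjusted p = 0.005), Aoc1 at least 176-fold (0.0219), Degs2 at least 80.8-fold (0.0073) and Ggt1 at least 62.2-fold (0.0067), each measured on 0 of 4 preimmortal arrays. Gpx2 (−6.52 ± 1.44, adjusted p = 0.0088), the brush border myosin Myo1a (−6.64 ± 1.37, 0.006) and Rarres2 (−6.43 ± 2.02, 0.0391) fell. Of the key genes, Cdkn2a, which encodes the p16 and p19 inhibitors of growth, was at least 15.9-fold higher (adjusted p = 0.0235, 1 of 3). Krt8 was at least 370-fold lower (adjusted p = 0.0365, 3 of 4) and the stem cell receptor Lgr5 at least 8.99-fold (0.0308, 1 of 4). Differences that did not pass were those of Apc (0.56), Trp53 (−0.08), Tert (−0.99), Car1 (−1.36), Krt19 (−3.10), Cdkn2b (0.92), Cdkn1a (1.29), Mdm2 (1.71), Mki67 (−1.35) and Myc (0.39).

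**Figure D1:**
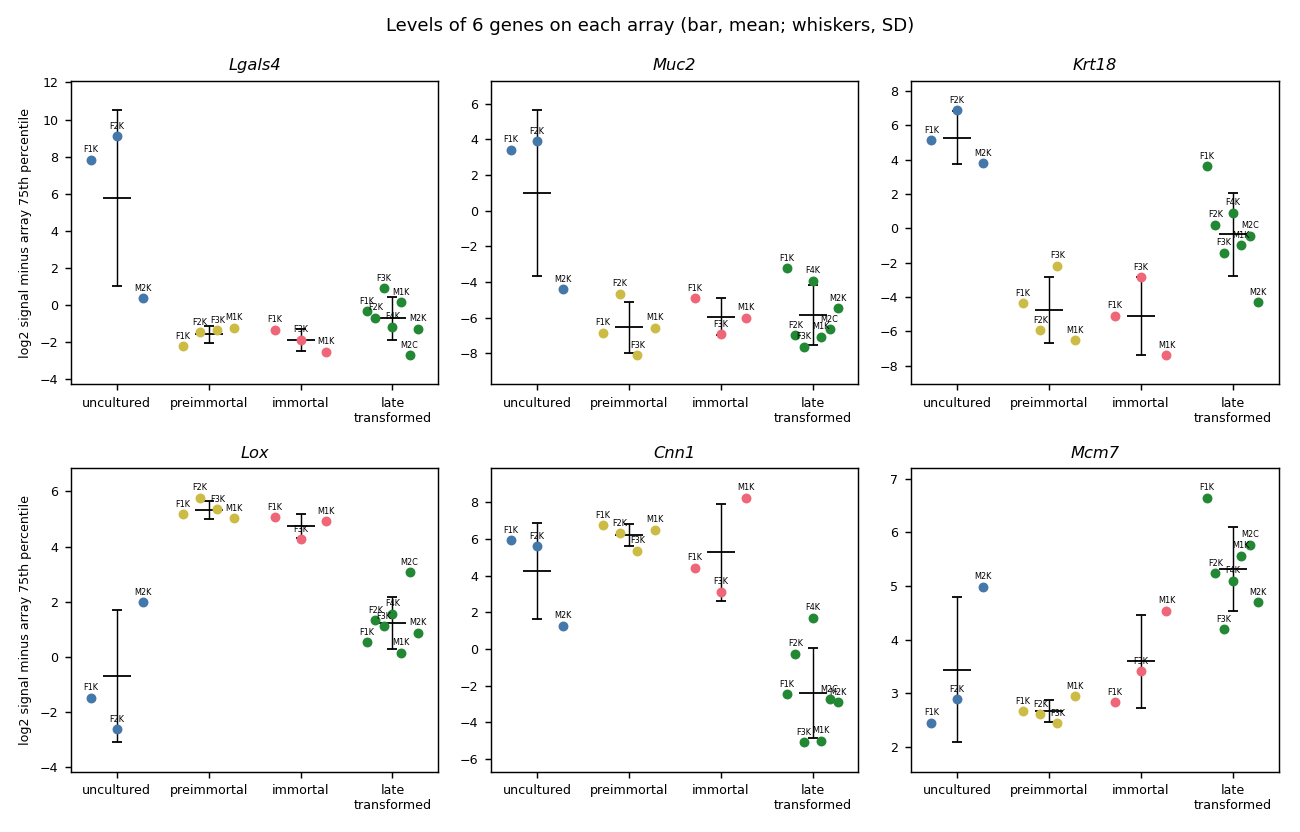
Log2 signal minus the array's 75th percentile of 6 genes (vertical axes) on each array, labelled by line, in the 4 groups (horizontal axes), with group means as bars and SDs as whiskers. Lgals4 lies at 7.83 and 9.11 on the arrays labelled uncultured F1K and F2K and at 0.35 on uncultured M2K, and Cnn1 and Lox have lower means in late transformed (−2.39 and 1.23) than in preimmortal cells (6.24 and 5.33).

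The split of calls turned with scaling: 486 higher and 3989 lower with the percentile over probes well above background, 1760 and 1644 with quantile normalization, and 4167 and 1285 with median centring. The deposited table called 8212 genes, 1793 of them also called here in the same direction and 27 in the opposite one. Without both uncultured M2K and late transformed F1K 10152 genes were called. Within scan day 4 (preimmortal F3K and M1K against uncultured F2K) all 3558 called genes and 14 of 14 lists had the same direction. Within slide 6, with the array labelled uncultured M2K, 3384 genes and 5 of 14 lists had it. The exceptions were goblet, enteroendocrine, intestinal transcription factor, epithelial junction, leukocyte, endothelial, p53 target, oncogene and tumour-lower lists. Slide as a block, resting on uncultured M2K and indirectly F1K, called 187 genes. Of the 14 lists mesenchymal (adjusted p = 0.0075) and interferon response genes (0.0115) stayed called, the other 12 lying at 0.178 to 0.527. With line as a block the calls of Hk1 (adjusted p = 0.0505) and Cdh2 (0.0666) were lost and Mdm2 passed (0.0129). The count was 952 without uncultured F1K, 956 without uncultured F2K, 8260 without uncultured M2K and 5651 without late transformed F1K. It was 2133, 1656 and 1801 without preimmortal F3K, F2K and F1K.

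Immortal and preimmortal cells frame the step to immortal growth. As a list, 31 proliferation genes lay higher in immortal cells (relative median 0.66, adjusted p = 0.0011, or adjusted p = 0.847 with an estimated correlation). So did 24 chromosome segregation genes (relative median 0.59, adjusted p = 0.0208, or adjusted p = 0.847 with an estimated correlation). The 16 glycolysis genes lay lower (relative median −0.67, adjusted p = 0.0091, or adjusted p = 0.847 with an estimated correlation), and so did 13 endothelial markers (relative median −1.14, adjusted p = 0.0239, or adjusted p = 0.847 with an estimated correlation). By limma 0 members of these 4 lists passed over all genes and 0 adjusted over the list alone. The median over all genes was −0.15, and 953 genes had an unadjusted p under 0.05.

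A single transcript was called, that of probe A_51_P492761, which has no gene symbol here and was named after its value was seen. It was higher by at least 2.86 on the log2 scale (adjusted p = 0.0407), well above background on 3 of 3 immortal and 0 of 4 preimmortal arrays. The key genes did not pass. Among regulators of growth, Myc differed by 1.12 ± 0.59, Ccnd1 by −1.34 ± 0.77, Cdkn2a by −0.99 ± 1.46, Cdkn2b by −0.96 ± 1.12, Cdkn1a by −0.65 ± 0.73, Trp53 by 0.24 ± 0.65 and Mdm2 by 0.02 ± 0.79. Tert, the catalytic subunit of telomerase, differed by −0.86 ± 0.74 and the proliferation marker Mki67 by 0.53 ± 0.81. Vim differed by −0.70 ± 0.54, Cdh2 by −0.47 ± 0.78, Zeb1 by 0.31 ± 0.56, Krt19 by −1.61 ± 2.66, Car1 by −0.67 ± 0.72 and Apc by 0.23 ± 0.38. Cdh1, Cdx2, Lgr5 and Muc2 were well above background on at most 1 array of either group, and Krt8 on 1 of 3 immortal arrays. Genes of chromosomes 4 and 7 lay lower (relative medians −0.22 and −0.19, both adjusted p = 0.0245, or adjusted p = 0.993 with an estimated correlation). These 2 chromosome calls became 1 without preimmortal F3K, F2K or F1K and 0 without immortal F3K, and 0 with line or slide as a block or in the deposited table.

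The proliferation call was lost without immortal M1K (adjusted p = 0.994, with a median of −0.19, not relative to all genes). That of segregation genes was lost without preimmortal F3K (0.127), immortal F3K (0.0698) and immortal M1K (0.874, with a median of −0.26), and that of glycolysis genes without immortal F3K (0.0698). That of endothelial markers was lost without preimmortal F3K or F1K and immortal F3K or M1K (0.0735 to 0.224). The single call became 0 without preimmortal F3K, M1K or F2K, immortal F3K or M1K, uncultured F1K, or late transformed M1K, F4K, F3K or M2C. It became 5 without late transformed F1K, 2 without late transformed F2K or M2K, 7 without uncultured M2K and 3 without uncultured F2K. Within scan day 4 and within slide 4 all 4 lists and the called transcript had the same direction, and within slide 6 the transcript and glycolysis genes had it. Slide as a block kept the calls of proliferation genes (adjusted p = 0.0211) and endothelial markers (adjusted p = 0.0088) but not of glycolysis (0.0815) or segregation genes (0.0708). Line or slide as a block left 0 called genes. The deposited table called 1 other gene, and 63 were called without both uncultured M2K and late transformed F1K.

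In late transformed against immortal cells, the step to transformation, stromal and contractile lists fell and cell cycle lists rose, by the preset correlation alone. Cnn1, the calponin of smooth muscle, was at least 184-fold lower (adjusted p = 0.0283, measured on 6 of 7 late transformed arrays), and Lox changed by −3.52 ± 0.76 (adjusted p = 0.0405). The imprinted genes Grb10, for an adaptor of growth factor receptors, and Cdkn1c, for a kinase inhibitor of the cell cycle, were at least 133-fold (adjusted p = 0.0249, 3 of 7) and at least 47.8-fold lower (adjusted p = 0.0283, 5 of 7). The chemokine Ccl5 rose by 4.42 ± 0.80 (adjusted p = 0.0283) and the cell cycle transcription factor E2f2 by 3.53 ± 0.79 (adjusted p = 0.0458). The probes of Cnn1 and Grb10 lie on chromosome 9 at 21913058 to 21913117 and chromosome 11 at 11830965 to 11831024. 182 genes were called, 89 higher and 93 lower, with a median over all genes of 0.37.

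Of 11 smooth muscle markers 2 fell, Cnn1 and Actg2 (at least 13.0-fold lower, adjusted p = 0.0321, 6 of 7). The other 9 did not pass, and 3 were lower adjusted over the list alone, at a relative median of −2.36 (adjusted p = 2.18e-06, or adjusted p = 0.171 with an estimated correlation). Of 15 imprinted genes 3 fell and 12 did not pass, with 5 lower adjusted over the list alone and a relative median of −2.26 (adjusted p = 3.65e-07, or adjusted p = 0.109 with an estimated correlation). Of 17 fibroblast and myofibroblast markers 1 fell, Fbn1 (−2.16 ± 0.49, adjusted p = 0.0493). The other 16 did not pass, and 5 were lower adjusted over the list alone, at a relative median of −1.46 (adjusted p = 1.27e-07, or adjusted p = 0.121 with an estimated correlation). Of 22 mesenchymal and EMT genes 2 fell, Lox and Itgb1 (−1.98 ± 0.43, adjusted p = 0.0405). The other 20 did not pass, and 2 were lower adjusted over the list alone, at a relative median of −1.5 (adjusted p = 3.65e-07, or adjusted p = 0.375 with an estimated correlation).

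Proliferation genes rose as a list (relative median 1.11, adjusted p = 1.27e-07, or adjusted p = 0.47 with an estimated correlation). Of its 31 members 0 passed over all genes by limma, and 9 were higher adjusted over the list alone. DNA repair genes rose likewise (relative median 0.96, adjusted p = 1.04e-05, or adjusted p = 0.375 with an estimated correlation), with 0 of 22 passing and 9 higher adjusted over the list alone. Chromosome segregation genes also rose as a list (relative median 1.1, adjusted p = 1.94e-05, or adjusted p = 0.47 with an estimated correlation, and 0.0603 without immortal F1K). Of these 24 genes 0 passed over all genes and 0 adjusted over the list alone. Of 23 interferon response genes 1 rose, Cxcl10 (at least 21.0-fold, adjusted p = 0.0367, measured on 2 of 3 immortal arrays). The other 22 did not pass, and 4 were higher adjusted over the list alone, at a relative median of 2.01 (adjusted p = 0.000116, or adjusted p = 0.47 with an estimated correlation, and 0.537 without immortal M1K). Genes higher in human colorectal tumours lay lower (relative median −0.66, adjusted p = 0.0011, or adjusted p = 0.218 with an estimated correlation), with 0 of 33 passing and 2 lower adjusted over the list alone. Senescence-associated secreted factors lay lower too (relative median −1.51, adjusted p = 0.0399, or adjusted p = 0.375 with an estimated correlation), with 0 of 20 passing and 1 higher and 1 lower adjusted over the list alone. That call was lost without late transformed F1K, M1K, M2K or M2C and without immortal F3K or F1K (0.0576 to 0.128), in the deposited table (0.0698) and without the arrays labelled uncultured M2K and late transformed F1K (0.147). Among all genes 3005 had an unadjusted p under 0.05.

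Tspan7 (4.28 ± 0.80, adjusted p = 0.0284), the corepressor Rcor2 (3.91 ± 0.76, 0.0314) and Tcim (3.67 ± 0.75, 0.0341) rose. The growth factor Vegfd (−4.22 ± 0.82, adjusted p = 0.0314), Rnase4 (−3.55 ± 0.55, 0.0249), the phosphatase Dusp1 (−3.39 ± 0.75, 0.0428) and Nudt6 (−3.33 ± 0.67, 0.0332) fell. Sntg1 was at least 18.4-fold lower (adjusted p = 0.0249), Tchh at least 9.55-fold (0.0283), the matrix gene Aspn at least 8.65-fold (0.0455) and Zdhhc14 at least 5.37-fold (0.0386), each measured on 0 of 7 late transformed arrays. Krt8 was at least 67.3-fold higher without passing (adjusted p = 0.207, measured on 1 of 3 immortal arrays), with late transformed levels from −4.55 on M2K to 6.30 on the array labelled F3K. Other key genes that did not pass were Krt19 (3.66 ± 2.40), Mki67 (1.66 ± 0.73), Zeb1 (−1.49 ± 0.50), Cdh2 (−1.13), Vim (0.99), Trp53 (1.06), Mdm2 (0.90), Cdkn1a (0.19), Cdkn2a (−1.21), Cdkn2b (−0.59), Myc (−0.03), Ccnd1 (0.49), Apc (−0.48) and Car1 (1.06), while Tert was above background on 3 of 7 late transformed arrays and Cdx2, Lgr5, Muc2 and Cdh1 on at most 1 array of either group.

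Genes of chromosomes 19 and 11 lay higher (relative medians 0.31 and 0.22, adjusted p = 0.0034 and 0.0159). Those of chromosomes 13, 18, 3 and 9 lay lower (−0.31, −0.30, −0.23 and −0.21, adjusted p = 0.0159, 0.0159, 0.0452 and 0.0457). All 6 had adjusted p = 0.996 with an estimated correlation. In the deposited table chromosomes 3 and 9 lost the call (0.25 and 0.102) and chromosome 8 passed, lower too (0.0193), and without the arrays labelled uncultured M2K and late transformed F1K chromosome 9 lost it (0.0822). The 6 calls became 3 without late transformed M1K, 0 without immortal M1K and 2 without the array labelled late transformed F3K.

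All 182 called genes and 10 lists had the same direction within slide 3 and within scan day 4. Within slide 4, 180 genes and 5 lists had it, without proliferation, segregation, DNA repair and tumour-higher genes and senescence factors. Slide as a block left 2 genes and 9 lists (senescence factors adjusted p = 0.192), and line as a block gave 314 genes. Line as a block ended the calls of Ccl5, Rcor2, Dusp1, Fbn1, Aspn and Zdhhc14 (adjusted p = 0.0526 to 0.109), and Krt8 passed with it (0.0435). The count was 73, 99, 91 and 66 without preimmortal F3K, M1K, F2K and F1K, and 3, 54 and 2 without immortal F3K, M1K and F1K. It was 108, 7 and 120 without late transformed F2K, M1K and F3K, and 319 without uncultured M2K. The split was 45 higher and 137 lower with quantile normalization and 36 and 147 with median centring. The deposited table called 562 genes, 96 of them also called here in the same direction. Without both uncultured M2K and late transformed F1K 539 genes were called.

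Late transformed against preimmortal cells compares the ends of the culture. Genes of DNA replication and mitosis rose. Mcm7, a subunit of the replicative helicase, rose by 2.65 ± 0.52 (adjusted p = 0.0043), from 2.67 ± 0.21 (n = 4) to 5.31 ± 0.79 (n = 7, limma), and the mitotic kinesin Kif11 by 2.66 ± 0.55 (adjusted p = 0.0062, measured on 6 of 7 late transformed arrays). Contractile genes fell, with Cnn1 at least 358-fold lower (adjusted p = 0.000818, measured on 6 of 7) and the actin-binding Tagln at −6.02 ± 1.34 (adjusted p = 0.0115). Grb10 was at least 179-fold lower (adjusted p = 0.000358, 3 of 7) and Cdkn1c at least 187-fold (adjusted p = 0.000247, 5 of 7). The probe of Mcm7 lies on chromosome 5 at 138605925 to 138605984. 2108 genes were called, 1408 higher and 700 lower, with a median over all genes of 0.14.

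Of 31 proliferation genes 19 rose and 12 did not pass, with 25 higher adjusted over the list alone and a relative median of 2.00 (adjusted p = 2.06e-11, or adjusted p = 0.357 with an estimated correlation), and Mki67 rose by 2.20 ± 0.66 (adjusted p = 0.044). Of 24 chromosome segregation genes 12 rose and 12 did not pass, with 18 higher adjusted over the list alone and a relative median of 1.82 (adjusted p = 1.15e-07, or adjusted p = 0.357 with an estimated correlation). The condensin Smc2 rose by 2.63 ± 0.59 (adjusted p = 0.0098) and the checkpoint kinase Bub1b by 2.64 ± 0.57 (adjusted p = 0.0078). Of 22 DNA repair genes 11 rose and 11 did not pass, with 17 higher adjusted over the list alone and a relative median of 1.53 (adjusted p = 3.06e-07, or adjusted p = 0.28 with an estimated correlation). The mismatch repair gene Msh6 rose by 1.91 ± 0.36 (adjusted p = 0.0033).

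Of 14 telomerase and telomere genes 4 rose and 10 did not pass, with 8 higher adjusted over the list alone and a relative median of 0.73 (adjusted p = 0.045, or adjusted p = 0.245 with an estimated correlation, and 0.153 with line as a block). Dyskerin, Dkc1, rose by 1.74 ± 0.41 (adjusted p = 0.012) and Pot1b was at least 2.86-fold higher (adjusted p = 0.0111, measured on 1 of 4 preimmortal arrays), while Tert was at least 1.55-fold lower without passing (adjusted p = 0.329, 3 of 7). The list's call was lost without preimmortal F3K or F1K and late transformed F2K, M2K or M2C, each in turn (0.0511 to 0.0813), and in the deposited table (0.0754). Of 23 interferon response genes 2 rose, Cxcl10 by 3.43 ± 0.86 (adjusted p = 0.0175) and Oas1a at least 21.5-fold (adjusted p = 0.0336, 2 of 4). The other 21 did not pass, and 2 were higher adjusted over the list alone, at a relative median of 1.31 (adjusted p = 0.0354, or adjusted p = 0.748 with an estimated correlation). That call was lost with line as a random block (0.0547), without preimmortal M1K (0.218) and without late transformed F2K, F4K or F3K (0.114 to 0.125).

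Of 11 smooth muscle markers 6 fell and 5 did not pass, with 8 lower adjusted over the list alone and a relative median of −3.79 (adjusted p = 1.15e-07, or adjusted p = 0.127 with an estimated correlation), and Actg2 was at least 18.1-fold lower (adjusted p = 0.0013, 6 of 7). Of 17 fibroblast and myofibroblast markers 5 fell and 12 did not pass, with 7 lower adjusted over the list alone and a relative median of −1.99 (adjusted p = 1.15e-07, or adjusted p = 0.127 with an estimated correlation). Postn changed by −5.96 ± 1.17 (adjusted p = 0.0043), smooth muscle actin, Acta2, by −3.81 ± 0.71 (adjusted p = 0.0033) and Fbn1 by −2.94 ± 0.45 (adjusted p = 0.000949). Of 22 mesenchymal and EMT genes 4 fell and 18 did not pass, with 7 lower adjusted over the list alone and a relative median of −1.17 (adjusted p = 2.43e-05, or adjusted p = 0.357 with an estimated correlation). Lox changed by −4.10 ± 0.69 (adjusted p = 0.0018) and Itgb1 by −2.11 ± 0.39 (adjusted p = 0.0029), and Vim differed by 0.29 ± 0.44 (adjusted p = 0.781).

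Of 15 imprinted genes 6 fell and 9 did not pass, with 6 lower adjusted over the list alone and a relative median of −1.52 (adjusted p = 3.63e-05, or adjusted p = 0.127 with an estimated correlation). Of 33 genes higher in human colorectal tumours 2 fell, the collagen Col11a1 (at least 37.7-fold, adjusted p = 0.0016, 6 of 7) and the dipeptidase Dpep1 (at least 57.6-fold, adjusted p = 0.0101, 3 of 7). The other 31 did not pass, and 2 were lower adjusted over the list alone, at a relative median of −0.83 (adjusted p = 0.0079, or adjusted p = 0.28 with an estimated correlation). Of 20 senescence-associated secreted factors 3 fell and 17 did not pass, with 5 lower and 1 higher adjusted over the list alone and a relative median of −0.77 (adjusted p = 0.0493, or adjusted p = 0.357 with an estimated correlation). Igfbp7 changed by −2.75 ± 0.55 (adjusted p = 0.0049) and the cytokine Il6 was at least 7.94-fold lower (adjusted p = 0.011, 6 of 7). The list's call was lost without preimmortal F3K, F2K or F1K, late transformed F1K, M1K, M2K, F3K or M2C, immortal F1K or uncultured M2K (0.0524 to 0.135), in the deposited table (0.112) and without both uncultured M2K and late transformed F1K (0.205). Of 16 glycolysis genes 1 fell, Eno1 (−1.38 ± 0.38, adjusted p = 0.0273), 15 did not pass, and 1 was lower adjusted over the list alone, at a relative median of −0.70 (adjusted p = 0.0298, or adjusted p = 0.748 with an estimated correlation), and the call was lost without late transformed F1K or M2K, without preimmortal F2K, and without both uncultured M2K and late transformed F1K (0.0501 to 0.105).

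N4bp3 (4.11 ± 0.49, adjusted p = 0.000207), Gchfr (4.18 ± 0.63, 0.0011), Tcim (4.02 ± 0.68, 0.0018), Rcor2 (3.94 ± 0.69, 0.0024) and the integrin Itgb7 (4.77 ± 1.36, 0.0338) rose. Ephx2 (−4.90 ± 1.06, adjusted p = 0.0082), Tmem37 (−4.61 ± 0.98, 0.0076) and Vegfd (−4.59 ± 0.75, 0.0016) fell. Smpdl3a was at least 102-fold lower (adjusted p = 0.0035), Tchh at least 45.6-fold (0.000158) and Aspn at least 37.3-fold (0.00048), each measured on 0 of 7 late transformed arrays. Key genes that did not pass were Krt8 (5.69 ± 2.26), Trp53 (1.31 ± 0.53), Myc (1.08 ± 0.49), Zeb1 (−1.18 ± 0.46), Cdh2 (−1.60 ± 0.64), Cdkn2a (−2.21 ± 1.19), Cdkn2b (−1.56), Cdkn1a (−0.46), Mdm2 (0.93), Ccnd1 (−0.85), Apc (−0.24), Krt19 (2.06) and Car1 (0.39), while Cdh1, Cdx2, Lgr5 and Muc2 were above background on at most 1 array of either group. Genes of chromosome 19 lay higher (relative median 0.33, adjusted p = 0.0053, or 0.933 with an estimated correlation). Chromosome calls became 0 without the array labelled late transformed F3K and 2 without preimmortal M1K or with slide as a block.

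**Figure D2:**
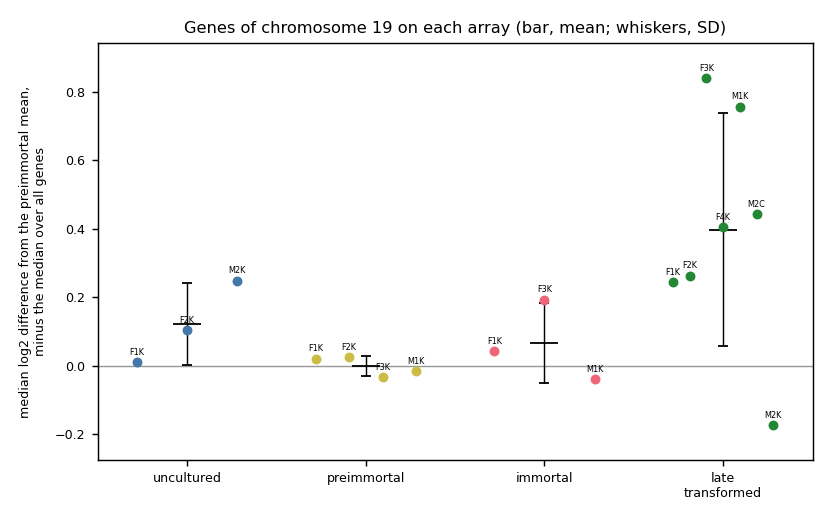
Median over the 724 tested genes of chromosome 19 of the log2 difference from the preimmortal mean, minus the median over all genes (vertical axis), on each array, labelled by line, in the 4 groups (horizontal axis), with group means as bars and SDs as whiskers. Late transformed arrays lie between 0.24 and 0.84 except M2K at −0.17, and preimmortal arrays between −0.03 and 0.03.

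Within slide 4, 2075 of 2108 called genes and 10 of 12 lists (not senescence factors or glycolysis genes) had the same direction. Within scan day 4 all 2108 genes and 12 lists had it. Slide as a block left 0 genes by limma and 6 lists. It ended the calls of mesenchymal genes (adjusted p = 0.11), tumour-higher genes (0.0885), telomere genes (0.0885), interferon genes (0.235) and senescence factors (0.11), and turned the glycolysis median to 0.70 (0.133). Line as a block ended the calls of Mki67 (adjusted p = 0.0982) and Eno1 (0.0976), and Krt8 passed with it (0.0201). The count was 1277, 998 and 1216 without preimmortal F3K, F2K and F1K. The split was 973 higher and 832 lower with quantile normalization and 830 and 700 with median centring. The deposited table called 2831 genes, 1199 higher and 1632 lower, 1178 of them also called here in the same direction. Without both uncultured M2K and late transformed F1K 3434 genes were called.

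Late transformed against uncultured cells comes nearest to tumour against normal tissue. With the preset correlation alone, the proliferation list rose and lists of gut epithelium and some other cell types fell. The helicase subunit Mcm4 rose by 2.43 ± 0.58 (adjusted p = 0.0348) and the kinetochore gene Zwint by 2.46 ± 0.47 (adjusted p = 0.0288). Lgals4 fell by 6.50 ± 1.29 on the log2 scale (adjusted p = 0.0292), and Robo4, a receptor of endothelial cells, was at least 568-fold lower (adjusted p = 0.0095, measured on 1 of 7 late transformed arrays). The probes of Zwint and Robo4 lie on chromosome 10 at 72137537 to 72137596 and chromosome 9 at 37221537 to 37221596. 2096 genes were called, 938 higher and 1158 lower, with a median over all genes of −0.12.

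Of 31 proliferation genes 9 rose and 22 did not pass, with 15 higher adjusted over the list alone and a relative median of 1.85 (adjusted p = 3.19e-09, or adjusted p = 0.278 with an estimated correlation). Cdc45 rose by 2.01 ± 0.48 (adjusted p = 0.0341), and Mki67 differed by 0.85 ± 0.73 (adjusted p = 0.407). Of 24 chromosome segregation genes 2 rose, Zwint and Mad1l1 (1.65 ± 0.48, adjusted p = 0.0427), 22 did not pass, and 10 were higher adjusted over the list alone, at a relative median of 1.67 (adjusted p = 6.79e-07, or adjusted p = 0.278 with an estimated correlation). Of 22 DNA repair genes 5 rose and 17 did not pass, with 11 higher adjusted over the list alone and a relative median of 1.48 (adjusted p = 2.16e-06, or adjusted p = 0.278 with an estimated correlation), and Msh6 rose by 1.82 ± 0.39 (adjusted p = 0.0337). Of 22 mesenchymal and EMT genes 2 rose, Axl (1.89 ± 0.57, adjusted p = 0.0463) and Twist1 (at least 6.62-fold, adjusted p = 0.0414, measured on 2 of 3 uncultured arrays). The other 20 did not pass, and 4 were higher adjusted over the list alone, at a relative median of 1.61 (adjusted p = 0.000256, or adjusted p = 0.293 with an estimated correlation, and 0.06 without uncultured F2K).

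Of 16 glycolysis genes 2 rose, Pfkm (1.5 ± 0.44, adjusted p = 0.0443) and Hk1 (1.75 ± 0.52, adjusted p = 0.0464), 14 did not pass, and 4 were higher and 1 lower adjusted over the list alone, at a relative median of 1.18 (adjusted p = 0.0062, or adjusted p = 0.39 with an estimated correlation, and 0.162 without uncultured F1K). In the deposited table the list (adjusted p = 0.181) and Hk1 (adjusted p = 0.0172) lay lower. Of 22 oncogenes of colorectal cancer 4 rose and 18 did not pass, with 4 higher adjusted over the list alone and a relative median of 0.69 (adjusted p = 0.01, or adjusted p = 0.278 with an estimated correlation), and the call was lost without uncultured F1K (0.0982) and in the deposited table (0.172). The cell cycle kinase Cdk4 rose by 2.41 ± 0.71 (adjusted p = 0.0444) and Egfr by 2.14 ± 0.65 (adjusted p = 0.0477). Of 22 p53 targets 4 rose and 18 did not pass, with 6 higher and 1 lower adjusted over the list alone and a relative median of 0.93 (adjusted p = 0.0244, or adjusted p = 0.301 with an estimated correlation). Mdm2, for the ubiquitin ligase of p53, rose by 2.64 ± 0.71 (adjusted p = 0.039), and Eda2r was at least 7.49-fold higher (adjusted p = 0.0406, 1 of 3). The list's call was lost without uncultured F1K or F2K and without late transformed M2K or F3K (0.0536 to 0.0982).

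Of 20 epithelial junction and keratin genes 9 fell and 11 did not pass, with 15 lower adjusted over the list alone and a relative median of −3.22 (adjusted p = 9.74e-06, or adjusted p = 0.278 with an estimated correlation). Krt18 was at least 49.0-fold lower (adjusted p = 0.0354, 6 of 7), the claudin Cldn7 at least 71.6-fold (adjusted p = 0.0348, 1 of 7) and Cdh1 at least 20.3-fold (adjusted p = 0.0415, 0 of 7). Of 13 absorptive colonocyte markers 8 fell and 5 did not pass, with 10 lower adjusted over the list alone and a relative median of −5.37 (adjusted p = 1.84e-05, or adjusted p = 0.278 with an estimated correlation). Guca2a was at least 65.5-fold lower (adjusted p = 0.0341, 6 of 7) and Slc26a3 at least 27.0-fold (adjusted p = 0.0337, 0 of 7). Of 10 goblet and secretory markers 6 fell and 4 did not pass, with 8 lower adjusted over the list alone and a relative median of −6.71 (adjusted p = 3.39e-05, or adjusted p = 0.278 with an estimated correlation). Muc2 was at least 43.0-fold lower (adjusted p = 0.0333, 1 of 7), Spink4 at least 51.6-fold (adjusted p = 0.0358, 1 of 7) and Zg16 at least 153-fold (adjusted p = 0.0338, 1 of 7).

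Of 9 enteroendocrine markers 5 fell and 4 did not pass, with 9 lower adjusted over the list alone and a relative median of −4.38 (adjusted p = 3.82e-05, or adjusted p = 0.278 with an estimated correlation). Chgb was at least 78.8-fold lower (adjusted p = 0.0337, 2 of 7), Chga at least 31.0-fold (adjusted p = 0.0363, 0 of 7) and Pyy at least 20.7-fold (adjusted p = 0.0409, 6 of 7). Of 10 intestinal transcription factors 2 fell, among them Hnf4a (at least 3.51-fold, adjusted p = 0.043, 1 of 7). The other 8 did not pass, and 5 were lower adjusted over the list alone, at a relative median of −2.07 (adjusted p = 0.0237, or adjusted p = 0.293 with an estimated correlation), and the call was lost without late transformed F1K (0.0526) and without uncultured F2K (0.0931). Of 30 genes lower in human colorectal tumours 13 fell and 17 did not pass, with 19 lower adjusted over the list alone and a relative median of −2.45 (adjusted p = 4.66e-07, or adjusted p = 0.278 with an estimated correlation). Of 33 genes higher in human colorectal tumours 0 rose and 3 fell by limma, and as a list they did not pass (relative median −0.33, adjusted p = 0.881). The epithelial lists, and Lct, were again high on the arrays labelled uncultured F1K and F2K.

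Markers of other cell types fell too. Of 13 endothelial markers 7 fell and 6 did not pass, with 10 lower adjusted over the list alone and a relative median of −4.15 (adjusted p = 2.31e-06, or adjusted p = 0.278 with an estimated correlation), and Vwf was at least 39.6-fold lower (adjusted p = 0.0348, 3 of 7). Of 15 leukocyte markers 6 fell and 9 did not pass, with 12 lower adjusted over the list alone and a relative median of −3.28 (adjusted p = 7.84e-06, or adjusted p = 0.278 with an estimated correlation). Coro1a was at least 32.9-fold lower (adjusted p = 0.0337, 4 of 7) and the class II gene H2-Ab1 at least 77.1-fold (adjusted p = 0.0341, 0 of 7). Of 11 smooth muscle markers 8 fell and 3 did not pass, with 8 lower adjusted over the list alone and a relative median of −4.02 (adjusted p = 8.07e-05, or adjusted p = 0.278 with an estimated correlation, and 0.0923 in the deposited table). Cnn1 was at least 91.7-fold lower (adjusted p = 0.0327, 6 of 7) and the myosin Myh11 at least 45.6-fold (adjusted p = 0.0368, 3 of 7). Of 10 enteric glia and neuron markers 3 fell and 7 did not pass, with 3 lower adjusted over the list alone and a relative median of −1.97 (adjusted p = 0.0036, or adjusted p = 0.293 with an estimated correlation). S100b was at least 14.7-fold lower (adjusted p = 0.0341, 6 of 7) and Sox10 at least 4.82-fold (adjusted p = 0.0348, 3 of 7). Of 3 erythroid markers 1 fell, haemoglobin Hba-a1 (at least 58.9-fold, adjusted p = 0.0337, 2 of 7), 2 did not pass, and 3 were lower adjusted over the list alone, at a relative median of −2.98 (adjusted p = 0.0193, or adjusted p = 0.278 with an estimated correlation), and the call was lost in the deposited table (adjusted p = 0.978).

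**Figure D3:**
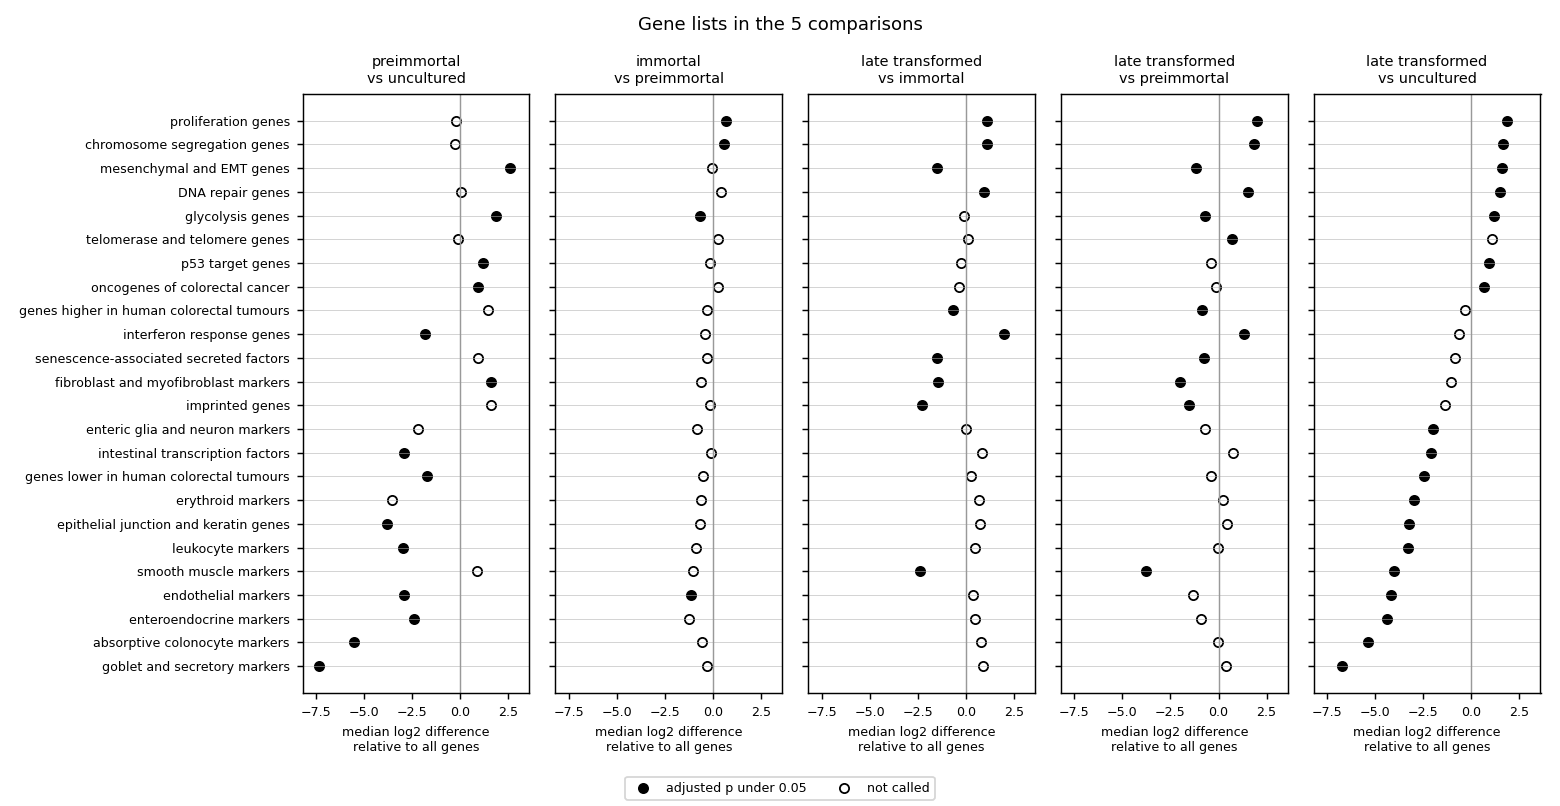
Median log2 difference of each gene list relative to the median over all genes (horizontal axes) in the 5 comparisons (panels), for the lists (vertical axis) called in at least 1 of them, with filled points for an adjusted p under 0.05 with the preset correlation and open points for the others. Goblet and secretory markers lie at −7.36 in preimmortal and −6.71 in late transformed against uncultured cells, and proliferation genes at 2.00 in late transformed against preimmortal cells.

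Steap1 (3.81 ± 0.94, adjusted p = 0.0354), the cytokine receptor Tnfrsf12a (3.70 ± 0.72, 0.0288), Cd109 (3.49 ± 0.92, 0.0384), haem oxygenase Hmox1 (3.42 ± 0.88, 0.0378) and Ccn4 (3.41 ± 1.05, 0.0494) rose. Myo1a (−4.98 ± 1.24, adjusted p = 0.0364), Postn (−4.65 ± 1.28, 0.0399), Tagln (−4.64 ± 1.34, 0.0454) and the Paneth cell defensin Defa3 (−4.37 ± 1.22, 0.0412) fell. Degs2 was at least 41.3-fold lower (adjusted p = 0.0333), Tspan18 at least 32.3-fold (0.0288), Misp at least 32.2-fold (0.0369) and Cd200 at least 27.2-fold (0.0288), each measured on 0 of 7 late transformed arrays. Key genes that did not pass were Vim (1.54 ± 0.49, adjusted p = 0.0533), Tert (at least 3.08-fold lower, 0.059, 3 of 7), Cdx2 (at least 16.5-fold lower, 0.0632, 1 of 7), Lgr5 (at least 3.42-fold lower, 1 of 7), Cdkn2a (at least 3.44-fold higher, 1 of 3), Myc (1.47 ± 0.54) and Ccnd1 (1.73 ± 0.70). The others were Zeb1 (1.13), Trp53 (1.22), Cdh2 (1.07), Cdkn1a (0.83), Cdkn2b (−0.63), Krt8 (−3.27), Krt19 (−1.04), Car1 (−0.97) and Apc (0.32). By camera 0 chromosomes were called here and in preimmortal against uncultured cells.

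Within slide 5 (uncultured F1K) and scan day 4 (uncultured F2K) all 2096 called genes and 18 lists had the same direction. Slide as a block left 0 genes by limma and 16 lists, without intestinal transcription factors (adjusted p = 0.335) and p53 targets (adjusted p = 0.431), and line as a block left 667 genes. Of the genes named here, those that had risen and lost their call with line as a block were Cdc45, Mad1l1, Twist1, Axl, Pfkm, Hk1, Cdk4, Egfr, Eda2r, Steap1 and Ccn4 (adjusted p = 0.0519 to 0.144). Those that had fallen and lost it were Cdh1, Cldn7, Guca2a, Slc26a3, Spink4, Zg16, Chga, Pyy, Hnf4a, S100b, Postn, Defa3, Degs2 and Misp (0.0508 to 0.077). The count was 0 without uncultured F1K or uncultured F2K, against 6934 genes at an unadjusted p under 0.05 with all arrays, and 8155 without uncultured M2K. It was 436, 1056, 501 and 544 without preimmortal F3K, M1K, F2K and F1K and 693 without immortal F3K. Without late transformed F1K, F2K, M1K, M2K, F3K and M2C it was 5888, 1, 1, 1123, 659 and 114, and it was 1 without the filter on dim probes. The split was 208 higher and 3042 lower with the percentile over probes well above background and 4073 and 991 with median centring. The deposited table called 9358 genes, 3230 higher and 6128 lower, 1399 of them also called here in the same direction and 19 in the opposite one. Without both uncultured M2K and late transformed F1K 10501 genes were called.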

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

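The tests of a mislabelled array and of an exchange of arrays were chosen only after the result was seen, and the shift of chromosome 19 over all late transformed arrays had been seen before its tests were written.

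Arrays far from the rest of their group were sought in 326 tests over the preimmortal and the late transformed arrays. In 36 of them the highest or lowest array lay apart from the nearest other by a large part of the group's range, where chance gives about 5%. Late transformed F1K stood apart in 25. Its levels were highest of the 7 for Cd200 (−3.00), Cdh1 (−2.60), Chga (−2.31), Degs2 (−2.09), Guca2a (−1.85), H2-Ab1 (−2.98), Misp (−0.78), Prl8a2 (−2.31), Slc26a3 (−2.16), Smpdl3a (−1.05), Tchh (−3.06) and Vwf (−2.06), and lowest for Cdkn2b (−2.09), but none of these was well above background on that array, so the ranks compare signals near background. As list medians of level minus the gene's mean over all arrays, it was highest for colonocyte (1.25), glia and neuron (1.68), enteroendocrine (1.71), epithelial junction (2.28), tumour-higher (1.43), tumour-lower (1.53), goblet (1.59), intestinal transcription factor (1.86) and leukocyte genes (1.35). It had 27.4% of spots well above background, a 75th percentile of log2 signal of 4.81 and a median CV of 62.4% between spots of the same probe, against 9.35% to 15.9% on the other late transformed arrays. Other arrays stood apart in fewer tests than chance gives. Late transformed M2K did so with Ggt1 (−6.44) and chromosome 3 (0.14), F4K with Rarres2 (4.74) and senescence factors (1.41), and M2C with Nudt6 (−4.04). Preimmortal F2K did so with Crct1 at 1.79, Folh1 at 2.78 and Mdm2 at 2.71, and preimmortal M1K with H2-Ab1 at −4.91, Mcm4 at 3.68 and Mki67 at 3.40.

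The arrays labelled uncultured F1K and F2K had low levels of the colon genes Car1 (−1.89 and −2.35) and Aqp8 (−1.84 and −2.12). Of 7 lists of other tissues, small intestine lay 6.47 and 10.9 above the mean of the cultured arrays, against 6.23 and 9.03 for colonocyte and 7.99 and 9.45 for goblet genes, with Fabp1 at 7.02 and 7.96 and Sis at 2.24 and 6.27. Bladder (2.46 and 2.44, with 2 genes also in the fixed lists), kidney (2.64 and 2.20), lung (1.79 and 1.69), liver (2.20 and 1.03), stomach (2.18 and 2.46) and skin genes (1.62 and 0.85) lay lower, and on uncultured M2K the 7 lists lay between −0.28 and 0.25. RNA of the small intestine may account for the low Car1 and Aqp8, but Fabp1 is also made in the colon. In the deposited columns, of unknown scale, colonocyte lay above small intestine genes on both. A difference along the gut or between mice was not tested.

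The array labelled uncultured M2K lay with the cultured lines, with r = 0.959 across genes against their mean and 0.75 against the other 2 uncultured arrays, while its deposited column gave 0.757 and 0.959. An exchange with the array labelled late transformed F1K is argued against, as that array had r = 0.728 with uncultured F1K and F2K and 0.877 with the other late transformed arrays, although its deviations from the group mean correlated at 0.522 and 0.398 with those of uncultured F1K and F2K and at −0.526 with those of uncultured M2K. A mislabelled sample may explain the pattern, though this was found on the same data. The deposited column also went against the male label, with Xist at 13.65 and Ddx3y at −0.11, and that of uncultured F2K, labelled female, had Ddx3y at 9.96. The scanner values of uncultured M2K lay closest to late transformed F4K (r = 0.974, Xist at 5.35). Which sample the array holds stays open, and no biological explanation was tested.

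Genes of chromosome 19 lay higher in late transformed arrays, at 0.84 (F3K), 0.76 (M1K), 0.44 (M2C), 0.40 (F4K), 0.26 (F2K) and 0.24 (F1K) relative to preimmortal cells, except at −0.17 on M2K. Within slides 3 and 4, late transformed minus the lone immortal array had medians of 0.2243 (lower) and 0.2382 (higher). So few arrays leave a slide batch open. The proximal and the distal genes both lay above the median of all genes on 6 of 7 late transformed arrays, so that a gain of the whole chromosome may account for it. F3K and M1K had the highest r across genes of late transformed arrays (0.972), and F3K carried Y-linked transcripts against its label, so they may not be independent lines. Uncultured M2K (0.25) and immortal F3K (0.19) lay high too. DNA was not measured.

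Other splits of the arrays into groups of the same sizes were counted, all 35 or a draw of 100. For called genes, 1 of 35 splits reached the real count in preimmortal against uncultured (3558, highest other 1232) and immortal against preimmortal (1, highest other 0). It was 1 of 100 in late transformed against immortal (182, highest other 104) and preimmortal (2108, highest other 62) and 3 of 100 against uncultured (2096, highest other 8512). As lines recur across groups, shares over all splits do not exclude chance. The single call ended without 1 of several arrays, and in the last comparison another split called more genes. The split with 8512 genes set late transformed F1K beside uncultured F1K and F2K, and uncultured M2K among the late transformed arrays, which points to a structure of the samples. Splits parting as many lines as the real one were too few for a share under 5%: 1 of 12, 1 of 8, 1 of 7, 1 of 5 and 2 of 6 reached the real count, in the same order. For shifted chromosomes chance could not be excluded: 35 of 35 (0, highest other 3), 15 of 35 (2, highest other 6), and 10, 72 and 100 of 100 splits (6, 1 and 0, highest other 8, 7 and 7) reached the real count.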

How the results depend on the processing

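Chosen after the data were seen were the fits without the arrays labelled uncultured M2K and late transformed F1K, without the 3 arrays whose sex genes went against the label, on the 9 arrays that followed their deposited column, on the deposited table without late transformed F3K and with scan day as a block. Outside the fits that leave out 1 array, counts stayed within 1.5 times in 151 cases and moved in 75, lists kept their side of the threshold in 1120, lost it in 175 and reversed in 5, and named genes kept it in 12210, lost it in 894, passed newly in 562 and reversed in 22. Leaving out 1 array, the numbers were 111 and 59 for counts, 927, 55 and 1 for lists and 9730, 972, 88 and 0 for genes. Spots near background, on late transformed F1K above all, limit what can be called lower, and the cause was not tested for any value below, except that fits with fewer arrays or groups have fewer samples.

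Counts of called genes are given in the order preimmortal against uncultured, immortal against preimmortal, and late transformed against immortal, preimmortal and uncultured (3558, 1, 182, 2108 and 2096), where they moved by over 1.5 times. Array weights gave 13535, 1410, 3752, 6381 and 12998, and the fit without the arrays labelled uncultured M2K and late transformed F1K gave 10152, 63, 539, 3434 and 10501. Slide as a block gave 187, 0, 2, 0 and 0. The first, the third and the last were 8212, 562 and 9358 in the deposited table and, without late transformed F3K, 8062, 473 and 8976, with 0 for the second. Scan day as a block gave 2251, 5, 9 and, for the last, 0. Median centring gave 5452, 0 and, for the last, 5064, and normexp 9936, 0 and 427. The second and last were 0 and 3646 with quantile normalization and 4 and 3250 with the percentile over probes well above background. The second, the third and the last were 0, 53 and 1 without the filter on dim probes, 0, 3 and 0 with only the 2 groups compared, and 0, 332 and 728 without the 3 arrays of another extraction version. The second and the third were 0 and 313 on the 9 arrays. The second alone was 14 with probes above background on every array of a group, 3 with the mean of probes, 0 with trend and robust moderation and 0 with sex as a covariate. Leaving out 1 array gave 952 to 8260, 0 to 7, 2 to 319, 998 to 2775 and 0 to 8155.

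The code gives the pairing, and line as a replicate block gave 0, 314 and 667 genes for the second, the third and the last comparison. It left 0 of 2 shifted chromosomes in immortal against preimmortal and ended 1 of 58 list calls (telomere genes, adjusted p = 0.153 in late transformed against preimmortal). Of 640 values of named genes it ended 49 calls and added 20. As a random block, line ended 1 list call (interferon genes, adjusted p = 0.0547 in late transformed against preimmortal) and added 4 calls of named genes. Neither block changed any other of the 58 list calls. Of lists that had not passed, 6 did with line as a fixed block: erythroid (0.0206) and imprinted (0.0153) in preimmortal against uncultured, leukocyte (0.0452) and DNA repair (0.035) in immortal against preimmortal, CDK inhibitors (0.045) in late transformed against immortal and fibroblast markers (0.0437) in late transformed against uncultured.

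Shifted chromosomes were 0 with an estimated correlation. In immortal against preimmortal (2) they were 0 with median centring, the deposited table with or without late transformed F3K, no filter and slide as a block, and 0 to 3 leaving out 1 array. In late transformed against immortal (6) they were 0 with normexp and no filter, 3 with median centring and without the 3 arrays whose sex genes went against the label, 2 in the deposited table without late transformed F3K, and 0 to 7 leaving out 1 array. In late transformed against preimmortal (1) they were 0 with no filter, the deposited table without late transformed F3K and without the 3 arrays, 2 with slide or scan day as a block, 3 without the arrays of another extraction version and on the 9 arrays, and 0 to 2 leaving out 1 array.

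Reversed in the deposited table, and without late transformed F3K in it, with sizes on its unknown scale, were Hk1 (−0.91 both times), Rcor2 (1.56) and Smpdl3a (−4.49) in preimmortal against uncultured. In late transformed against uncultured they were erythroid markers (−0.49 and −0.64), glycolysis genes (−1.42 and −1.40), Cdkn1a (−1.72 and −1.91), Hk1 (−1.36 and −1.31), Hoxb13 (−7.0 and −7.08), Lct (1.59 and 2.37), N4bp3 (−3.14 and −3.12), Pot1b (2.71 and 2.58) and Prl8a2 (−3.13 and −3.09). Hnf4a reversed in late transformed against immortal without late transformed F3K in that table (−2.98). Zmat3 reversed with the mean of its probes in preimmortal against uncultured (−0.36), segregation genes without immortal M1K in immortal against preimmortal (−0.26, where leaving out 1 array gave −0.26 to 1.14) and glycolysis genes with slide as a block in late transformed against preimmortal (0.70). In 10 other cases a list's median changed sign but its test kept its direction, with the call lost in 7, as for proliferation genes without immortal M1K (−0.19).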

Other observations

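Cdca7, Hoxa10 and Hoxb13 were chosen after their values were seen, from lists that did not pass as a whole. Of 12 posterior Hox genes, which pattern the hind end of the body, 2 rose in late transformed against immortal cells and 10 did not pass by limma, with 2 higher adjusted over the list alone. Hoxa10 was at least 38.9-fold higher and Hoxb13 at least 8.10-fold (both adjusted p = 0.0252), each measured on 0 of 3 immortal arrays. Against preimmortal cells they were at least 26.2-fold (adjusted p = 0.0039) and at least 5.90-fold higher (adjusted p = 0.0083), each measured on 1 of 4 preimmortal arrays. The list's relative median against immortal cells was 1.25 (adjusted p = 0.078, or adjusted p = 0.47 with an estimated correlation), and it passed with slide as a block (0.0019) and in the deposited table (0.0031). Against immortal cells the call of Hoxa10 was lost with quantile normalization, with slide as a block and without late transformed M1K, immortal F3K or immortal F1K (0.0502 to 0.13). That of Hoxb13 was lost with only the 2 groups compared, with slide or scan day as a block and without immortal F3K, M1K or F1K (0.0558 to 0.144). Against preimmortal cells both were lost with slide as a block (0.128 and 0.214). Their probes lie on chromosome 6 at 52181656 to 52181715 (Hoxa10) and chromosome 11 at 96057368 to 96057427 (Hoxb13).

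Of 17 crypt stem cell and Wnt target genes, 4 fell in preimmortal against uncultured cells (4 lower adjusted over the list alone, list adjusted p = 0.124). In late transformed against preimmortal cells 1 rose and 2 fell (2 higher and 2 lower adjusted over the list alone, list adjusted p = 0.671). Cdca7 was among both, with −2.76 ± 0.61 in preimmortal cells (adjusted p = 0.0086, or 0.0725 with median centring and 0.253 with slide as a block) and a rise of 3.59 ± 0.50 in late transformed cells (adjusted p = 0.000482, or 0.17 with slide as a block). CDK inhibitors, tumour suppressors and fatty acid oxidation genes did not pass as lists in the 5 comparisons. Fatty acid oxidation genes passed in the deposited table against uncultured cells (1.3e-08 in preimmortal and 5.87e-08 in late transformed cells). Tumour suppressors passed against uncultured cells without the arrays labelled uncultured M2K and late transformed F1K (0.0289 in preimmortal and 0.026 in late transformed cells).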
